A study of Homo sapiens with 4 samples.

How the data were processed

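RNA-seq was carried out on 4 libraries of cells labelled A549 that had been stained with an antibody against ICAM1 and sorted, 2 libraries from the ICAM1-high and 2 from the ICAM1-low subset. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a SMARTer mRNA kit. The authors deposited raw read counts per gene as whole numbers in a single table, with 1 column per library, each matched to its sample by its description. Per the submitters' processing notes, FastQC 0.10.1 and the genome build GRCh38 were used. The aligner, the counting program, its strand setting and its treatment of reads that match several genes are not given in the sources used here, so values of near-identical and overlapping genes are uncertain. The table lists 58735 gene identifiers, all of them in GENCODE release 29, from which positions were taken, and 58207 had a symbol in the gene name table. Of 885 list members, 3 could not be matched to an identifier.

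From these counts, genes were compared between ICAM1-high and ICAM1-low with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust estimation, TMM scaling and the default expression filter, with a minimum count of 10 and a minimum total of 15. A call is a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes are from this test throughout. TMM factors were 1.059 and 1.065 in the ICAM1-high and 0.939 and 0.944 in the ICAM1-low libraries. Fold changes are ICAM1-high minus ICAM1-low on the log2 scale, "fell by" and "rose by" refer to that scale, and levels are TMM-scaled counts per 1e6 counts (CPM) with the SD of 2 libraries. The common dispersion was 0.00133, a coefficient of variation of 3.6% between libraries of a subset. Library totals of 16272591 to 17638647 counts put the floor of 3 counts at 0.161 to 0.196 CPM per library. A gene with 0 counts in a subset was given as a lower bound against 3 counts over that subset, and a gene with 1 to 3 counts as a ratio with a 95% exact binomial interval. Such bounds and intervals cover counting error only.

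The design, the gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule named ICAM1, the 12 genes with the largest change in each direction among called genes with separated libraries and a mean of at least 5 CPM, the 6 most abundant called genes in each direction that changed at least 1.5-fold, and up to 4 members of each list with the smallest adjusted p. Noncoding, antisense and pseudogene names were left out, and some genes that the rule names are not reported here. Genes of the chromosome 9 region and those named as chosen later lie outside the rule. The 31 lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 31 lists. Counts given for a list are of its members that passed the expression filter. That filter keeps a gene abundant enough in a single subset, so members near 0 in the other subset could hardly come out equal. They covered NF-kB and TNF/IL-1 response, chemokines, interferon response, class I and class II antigen presentation, adhesion and immune ligands, mesenchymal genes, epithelial junctions, stem cell markers, G1/S and G2/M, hypoxia, NRF2 targets, lipid synthesis and the unfolded protein response. The others were p53 targets, immediate early genes, heat shock, EGFR/MAPK output, YAP/TEAD and TGF-beta targets, integrins, matrix proteases, lung epithelium, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, histones, and leukocyte, endothelial and fibroblast markers.

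The test was first run on simulated counts drawn from these libraries' means, with 50 genes changed at each of 4 sizes among 15899. It recovered 50% of genes changed 1.25-fold, 78% at 1.5-fold, 84% at 2-fold and 100% at 4-fold, with 6 false calls, 3.7% of all calls. The changed genes had a mean of at least 1 CPM and were split evenly between rises and falls. In the data 59.7% of genes were called, with large changes mostly upward, so these rates may not carry over. Alternatives were DESeq2 size factors in edgeR, library size only, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, omission of mitochondrial and ribosomal protein genes, stricter thresholds, and omission of each library in turn. With 1 library left in a subset, that library is assumed to vary like the other subset. Alternatives added after seeing the data left out genes under 1 CPM in ICAM1-low or removed the trend of fold change on transcript GC content. Pseudocounts planned for normalised values did not apply to counts.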

Results

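RNA was sequenced from cells labelled A549, a human lung adenocarcinoma line, after fluorescence-activated sorting on surface ICAM1, an adhesion glycoprotein bound by leukocyte integrins. The 4 libraries comprised 2 from the ICAM1-high subset and 2 from the ICAM1-low subset. Total counts were 17638647 and 17271825 in the ICAM1-high libraries and 16665362 and 16272591 in the ICAM1-low libraries. At least 1 count was recorded for 25709 and 25889 genes in the ICAM1-high libraries, and for 23674 and 23821 genes in the ICAM1-low libraries. The first principal component held 89.9% of the variance of log2 levels and separated the subsets, and the second held 6%. Libraries of one subset differed from each other by more than sampling noise, with a chi-square per degree of freedom of 2.88 for ICAM1-high and 1.82 for ICAM1-low. The labels do not say whether the libraries of a subset came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

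The comparison asks how gene expression differs between cells labelled A549 with high and low surface ICAM1. ICAM1-high libraries held more mRNA of interferon response, class I antigen presentation, heat shock, DNA replication and lipid synthesis genes. NRF2 targets and EGFR/MAPK output genes were lower in them, and so were 18 of 30 genes of a joint unfolded protein and integrated stress response list, of which 10 were higher. These lists were called by camera with a preset inter-gene correlation of 0.01. With an estimated one, 0 of 31 lists were called (lowest adjusted p = 0.199). The estimate was above 0.01 for the interferon (0.375), NRF2 (0.126), class I (0.125) and stress response (0.013) lists. It was 0.01 for DNA replication, 0.001 for EGFR/MAPK output, -0.017 for heat shock and -0.026 for lipid synthesis. The EGFR/MAPK, heat shock and lipid calls were thus lost without a correlation above the preset. With an estimated correlation, camera refers its statistic to the few degrees of freedom left by 4 libraries, not to the number of genes. That setting could thus hardly call a list, and its adjusted p-values do not show that correlation undid the calls. CDKN2A, CDKN2B and MTAP, which A549 is known to lack through a homozygous deletion, were higher in the same ICAM1-high libraries. Their counts go against the cell line label, so the list differences cannot be assigned to a change of state in A549 cells. Also higher were 5 of 7 fibroblast and 4 of 5 endothelial markers tested, out of 14 listed for each. Of those tested, 5 and 3 were under 1 CPM in ICAM1-low, and some passed the filter through ICAM1-high alone. Both list calls were lost when single libraries were left out or with scaling by library size alone. ICAM1 itself (ENSG00000090339, chromosome 19, 10270835 to 10286615, GRCh38) was at 113 ± 3.60 CPM (library-scaled counts per 1e6; SD, n = 2) in ICAM1-high and 4.75 ± 0.202 CPM (n = 2) in ICAM1-low. Its log2 fold change was 4.57 with a standard error (SE) of 0.10 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.38e-50). ICAM1 was the sorting marker, so this value checks the labels. Of 16250 genes tested, 4935 were higher and 4771 lower in ICAM1-high, 59.7% in all. At least 2-fold differences were found for 1752 higher and 765 lower genes, and at least 4-fold differences for 743 and 84. With scaling by library size alone, 6735 genes were higher and 3124 lower, so that the higher share of calls was 68.3% in place of 50.8%. That scaling raised the median log2 fold change of all genes by 0.17.

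**Figure D1:**
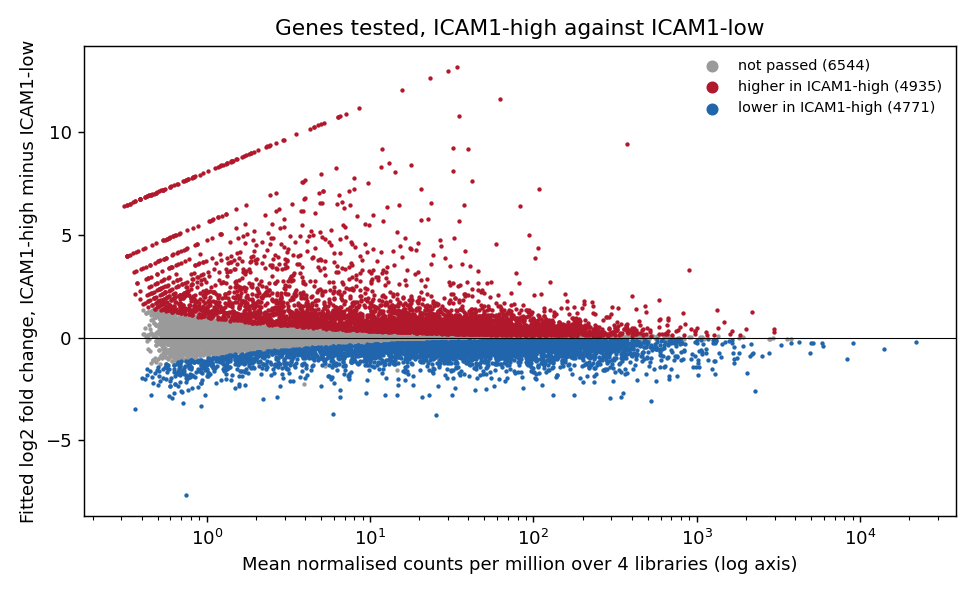
Fitted log2 fold change of each of the 16250 genes tested (vertical axis, ICAM1-high minus ICAM1-low) against its mean level in normalised CPM over 4 libraries (horizontal log axis). Red points are the 4935 genes higher and blue points the 4771 genes lower in ICAM1-high, and the slanted upper lines are genes with 0 or few counts in ICAM1-low, whose fitted values depend on the prior count.

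The genes with the largest rise in ICAM1-high were at or near 0 in ICAM1-low. PRSS21, a serine protease of the testis, was at 68.1 ± 2.93 CPM in ICAM1-high and 0 counts in both ICAM1-low libraries, at least 703-fold higher against a floor of 3 counts over the subset. By the same floor, the cell cycle inhibitor gene CDKN2A was at least 620-fold higher, DMD, which encodes dystrophin, at least 483-fold, and the metalloreductase gene STEAP4 at least 326-fold. PRSS56 was at least 176-fold higher, the folate receptor gene FOLR1 at least 147-fold, SIX2, a developmental transcription factor, at least 135-fold, and LRRC61 and the proteoglycan gene FMOD at least 132-fold each. SMIM10 was at least 108-fold higher. A single count in ICAM1-low was recorded for ALPP, the placental alkaline phosphatase, against 4594 in ICAM1-high, a ratio of 3845 (95% counting interval 690 to 151900). SLC1A3, a glutamate transporter, had 1 count against 2603, a ratio of 2179 (391 to 86090). Reads of ALPP may be shared with its near-identical relatives, and CDKN2A overlaps an antisense gene, so both values are uncertain to that extent. In all, 81 genes had at most 3 counts over the ICAM1-low libraries and at least 100 over the ICAM1-high libraries, and 0 genes showed the reverse. These 81 genes lay on 23 chromosomes.

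On chromosome 9, CDKN2A (ENSG00000147889, 21967753 to 21995301) had 2223 counts in ICAM1-high and 0 in ICAM1-low. Its neighbour CDKN2B (22002903 to 22009363), another cyclin-dependent kinase inhibitor gene, had 356 and 0 counts. MTAP (21802543 to 21937651), an enzyme of methionine salvage, had 922 and 9 counts, at a log2 fold change of 6.39 (SE 0.25). Its counts were 1 in ICAM1-low replicate 1 and 8 in replicate 2, so the size of that fold depends on single libraries. A549 is known to carry a homozygous deletion of CDKN2A and MTAP, so the counts of both ICAM1-high libraries go against their cell line label at these genes. Genes on either side were counted in both subsets. FOCAD had 1926 and 1785 counts, KLHL9 1826 and 1659, HACD4 188 and 95, IFNB1 165 and 109, IFNE 141 and 88, and DMRTA1 89 and 117. Of these 6, FOCAD (log2 fold change -0.15, adjusted p = 0.0557), KLHL9 (-0.12, adjusted p = 0.139), IFNB1 (0.34) and IFNE (0.42) did not pass the test, HACD4 rose by 0.73 (adjusted p = 0.00393) and DMRTA1 fell by 0.65 (adjusted p = 0.0241).

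**Figure D2:**
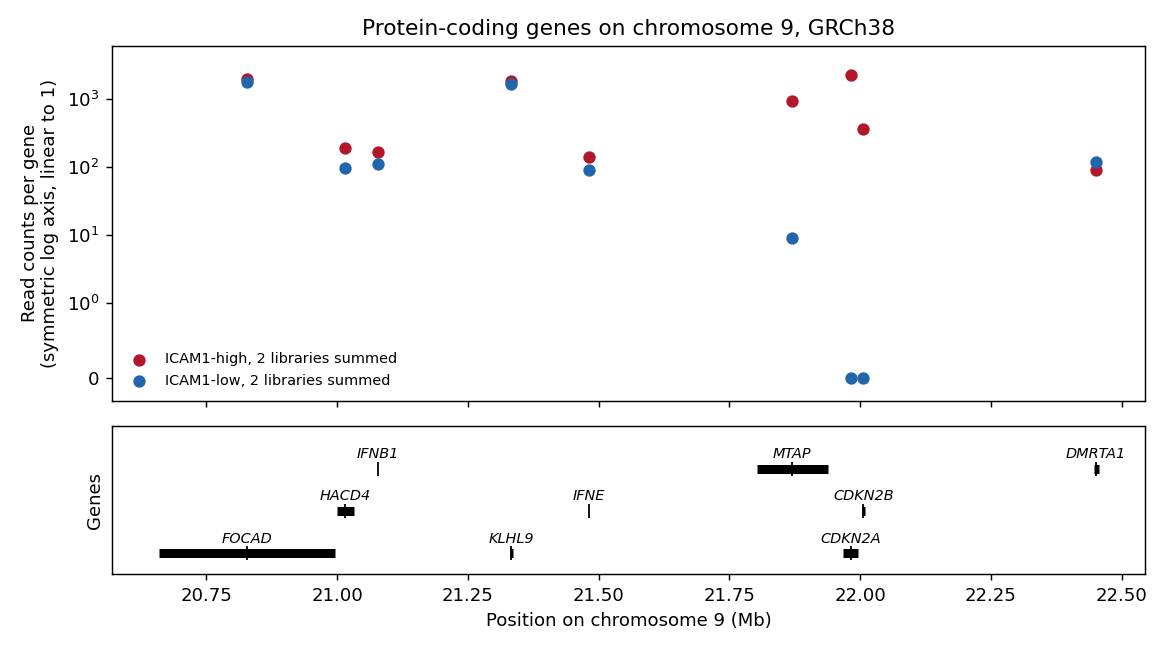
Upper panel, read counts per protein-coding gene, summed over the 2 libraries of each subset (vertical symmetric log axis), against position on chromosome 9 in Mb (GRCh38); lower panel, the genes drawn to scale with a tick at their midpoint. MTAP, CDKN2A and CDKN2B had 922, 2223 and 356 counts in ICAM1-high and 9, 0 and 0 in ICAM1-low.

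Among genes with a mean of at least 5 CPM, the 12 largest falls that the naming rule took were led by ULBP1 and FUT1. Called genes that the rule did not take reached a log2 fold change of -7.67. EREG, an EGFR ligand, was at 110.0 ± 10.7 CPM in ICAM1-high and 935 ± 2.45 CPM in ICAM1-low, a log2 fold change of -3.09 (SE 0.05, adjusted p = 2.3e-52). The related ligand AREG fell by 2.79 (SE 0.06). GDF15, a stress-induced cytokine, fell from 602 ± 16.7 to 81.9 ± 3.95 CPM (log2 fold change -2.88, SE 0.05), and stanniocalcin gene STC2 from 519 ± 8.57 to 67.9 ± 2.54 CPM (-2.93, SE 0.05). ULBP1, a ligand of the NK cell receptor NKG2D, fell by 3.78 (SE 0.12) and the fucosyltransferase gene FUT1 by 3.70 (SE 0.25). The other members of this group were CREB5 (-2.89), RAB39B (-2.88), CHAC1 (-2.81), ADM2 (-2.80), CBS (-2.78) and USP53 (-2.78), with SE between 0.05 and 0.21. Among abundant genes, KRT8 rose to 3074 ± 85.3 from 1290 ± 31.7 CPM, and TGM2, a transglutaminase, to 1144 ± 9.28 from 492 ± 21.4 CPM. ALDH1A1, a retinaldehyde dehydrogenase, fell to 5417 ± 214 from 11320 ± 197 CPM, ASPH to 1774 ± 63.6 from 3266 ± 22.7 CPM, and the neutrophil chemokine gene CXCL5 to 1636 ± 184 from 2790 ± 56.2 CPM.

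**Figure D3:**
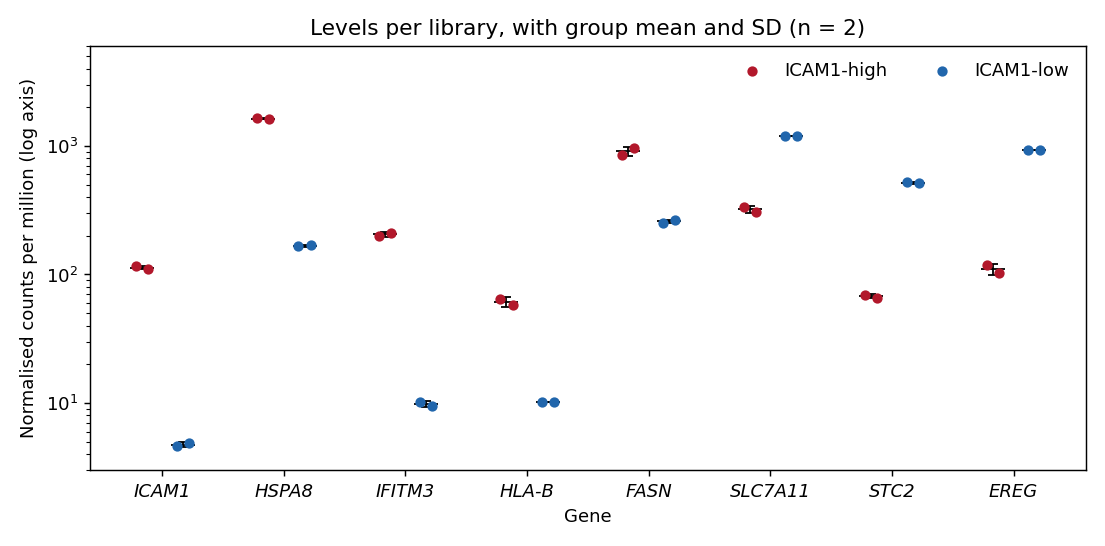
Normalised CPM (vertical log axis) of 8 genes in each library, with red points for ICAM1-high, blue points for ICAM1-low, and black dashes and bars for the mean and SD of each subset (n = 2). ICAM1, HSPA8, IFITM3, HLA-B and FASN were higher, and SLC7A11, STC2 and EREG lower, in both ICAM1-high libraries than in either ICAM1-low library.

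Interferon response genes rose together in ICAM1-high. Of 44 members, 42 rose and 0 fell, 42 when adjusted over the list alone, with a median log2 fold change of 1.53. The antiviral membrane protein gene IFITM3 was at 205 ± 7.41 CPM against 9.84 ± 0.460 (log2 fold change 4.38, SE 0.08), IFI6 at 141 ± 5.52 against 15.9 ± 0.262 CPM (3.14, SE 0.07), and IFI16, a DNA sensor, rose by 3.48 (SE 0.10). BST2, which encodes tetherin, was at 73.8 ± 0.58 against 0.843 ± 0.559 CPM. Of the 44, 7 had a mean under 1 CPM in ICAM1-low, in the same libraries in which the 81 genes above were at most at 3 counts. The list differed from other genes in the camera test (adjusted p = 5.54e-23) with a preset inter-gene correlation, and adjusted p = 0.288 with an estimated correlation. Class I antigen presentation genes also rose, 17 of 19 with 0 falling, and 17 adjusted over the list alone (median 1.01; adjusted p = 4.51e-09, and adjusted p = 0.263 with an estimated correlation). HLA-B rose by 2.59 (SE 0.10), B2M, the light chain of class I molecules, by 1.24 (SE 0.04), HLA-C by 1.23 (SE 0.05) and the chaperone gene CALR by 0.66 (SE 0.04). HLA-B and HLA-C are near-identical in part, so reads may be split between them.

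Heat shock genes rose in 18 of 19 cases and 1 fell, the same counts as adjusted over the list alone (median 0.90). HSPA8, a constitutive HSP70 chaperone, was at 1628 ± 14.1 CPM against 168 ± 3.10 CPM (log2 fold change 3.28, SE 0.04, adjusted p = 1.73e-62). HSP90AA1 rose by 1.34 (SE 0.04), HSP90AB1 by 0.75 (SE 0.04), the co-chaperone gene DNAJA1 by 1.52 (SE 0.05) and HSPA1A by 3.61 (SE 0.10), the last shared with its near-identical copy HSPA1B. The camera test gave adjusted p = 2.68e-10, and adjusted p = 0.199 with an estimated correlation. Genes of the G1/S transition and DNA synthesis rose in 32 of 38 cases and 1 fell, likewise 32 and 1 adjusted over the list alone (median 0.78; adjusted p = 1.79e-11, and adjusted p = 0.199 with an estimated correlation). Subunits of the replicative helicase led the list, with MCM5 rising by 1.63 (SE 0.06), MCM2 by 1.34 (SE 0.06), MCM6 by 1.23 (SE 0.06) and MCM4 by 1.17 (SE 0.05). Of 33 cholesterol and fatty acid synthesis genes, 24 rose and 2 fell, as adjusted over the list alone (median 0.45; adjusted p = 1.51e-06, and adjusted p = 0.216 with an estimated correlation). FASN, the fatty acid synthase, was at 911 ± 77.4 against 259 ± 8.13 CPM, and INSIG1, a regulator of sterol synthesis, rose by 1.69.

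NRF2 targets, which serve glutathione and redox metabolism, fell in 29 of 32 cases and 1 rose, as adjusted over the list alone (median -0.75; adjusted p = 1.24e-14, and adjusted p = 0.263 with an estimated correlation). The cystine transporter gene SLC7A11 was at 321 ± 18.4 against 1193 ± 3.19 CPM (log2 fold change -1.89, SE 0.04), thioredoxin reductase TXNRD1 fell by 1.70 (SE 0.04), SQSTM1 by 1.43 (SE 0.04) and the ferritin light chain gene FTL by 0.76 (SE 0.04). AKR1C3 (-0.98) and AKR1C2 (-0.77) also fell, although reads may be shared among these paralogs. The median fall of this list lies within the range of transcripts known to be abundant in A549 (-1.07 to -0.06) and exceeds their median of -0.35. RNA from other cells was not excluded as a cause of part of that fall. Of 25 genes of EGFR/MAPK output, 21 fell and 2 rose, as adjusted over the list alone (median -0.67; adjusted p = 5.91e-10, and adjusted p = 0.199 with an estimated correlation). Beside EREG and AREG, the receptor gene EPHA2 fell by 1.99 (SE 0.04) and PHLDA1 by 2.14 (SE 0.05). In the unfolded protein and integrated stress response list, 18 of 30 fell and 10 rose, as adjusted over the list alone (median -0.64; adjusted p = 6.59e-04, and adjusted p = 0.263 with an estimated correlation). The members with the smallest adjusted p, STC2, TRIB3 (-2.13), PPP1R15A (-1.87) and PSAT1 (-1.75), fell and are known targets of ATF4. Among the members that rose were MANF, SDF2L1 and HSPA5, named after their values were seen, by 1.06, 0.82 and 0.47. These 3 encode proteins of the endoplasmic reticulum.

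YAP/TEAD targets fell in 18 of 26 cases and 4 rose, as adjusted over the list alone (median -0.51; adjusted p = 4.41e-05, and adjusted p = 0.263 with an estimated correlation). CCN2 fell by 2.12, AJUBA by 1.99, AXL by 1.47 and CRIM1 by 1.07. Of 22 immediate early and AP-1 genes, 14 fell and 5 rose, or 15 and 5 adjusted over the list alone (median -0.49; adjusted p = 0.0015, and adjusted p = 0.295 with an estimated correlation). KLF6 fell by 1.79, DUSP1 by 1.52, FOSL2 by 1.42 and JUN by 1.07. The NF-kB and TNF/IL-1 response list, whose pathway is known to induce ICAM1, held 13 members that fell and 7 that rose among 28, or 14 and 8 adjusted over the list alone (adjusted p = 0.0264, and adjusted p = 0.377 with an estimated correlation). Its median was -0.089, -0.038 without ICAM1-low replicate 2, and 0.084 with scaling by library size alone. PTGS2, the inducible cyclooxygenase, was at 643 ± 45.5 against 3890 ± 92.8 CPM (log2 fold change -2.60, SE 0.04), NFKB2 fell by 1.48, and IER3 and PLAU were 2.38-fold and 2.37-fold lower. Without ICAM1-high replicate 2 this list was no longer called (adjusted p = 0.0733).

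Mesenchymal genes rose in 17 of 28 cases and 6 fell, or 17 and 7 adjusted over the list alone (median 0.38; adjusted p = 0.00286, and adjusted p = 0.263 with an estimated correlation). The collagen gene COL5A1 was at 191 ± 12.97 against 13.1 ± 0.963 CPM and the matrix protein gene SPARC at 83.8 ± 4.74 against 0.420 ± 0.0400 CPM, whereas AXL fell by 1.47. Markers of other cell types moved in the same libraries. Of 14 fibroblast markers 7 were abundant enough to test, of which 5 rose and 0 fell, as adjusted over the list alone (median 2.07; adjusted p = 0.0346, and adjusted p = 0.583 with an estimated correlation). COL1A1 rose by 2.81, LUM by 3.34, PDGFRB had 26 counts against 5, and FAP had 42 counts against 1. Of 14 endothelial markers 5 were tested, of which 4 rose and 1 fell, as adjusted over the list alone (median 2.29; adjusted p = 0.0346, and adjusted p = 0.295 with an estimated correlation). ENG rose by 2.29 and PECAM1 by 2.09, CDH5 had 64 counts against 1, and ERG was at least 24.8-fold higher against the floor of 3 counts. Most of these markers were under 5 CPM in ICAM1-high. In ICAM1-low, 5 of the 7 fibroblast and 3 of the 5 endothelial markers tested were under 1 CPM. LUM, FAP, PDGFRB, CDH5 and ERG passed the expression filter through ICAM1-high alone, so their rise was largely fixed by their being tested. SPARC of the mesenchymal list also passed it through ICAM1-high alone. The fibroblast call was lost without ICAM1-high replicate 2 (adjusted p = 0.0502) or ICAM1-low replicate 1 (0.0736, median 1.08) and with no filter on low counts (0.0589, median 0.97), and the endothelial call without ICAM1-high replicate 1 (0.0574) or 2 (0.0727). Both were lost with scaling by library size alone (0.0954 each).

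A call was also made for 5 further lists. G2/M genes rose in 21 of 40 cases and 9 fell, or 22 and 9 adjusted over the list alone (median 0.18; adjusted p = 0.0346, and adjusted p = 0.288 with an estimated correlation), with KIF20A rising by 1.78 and CCNB1 by 0.73 while CDC25B fell by 0.70 and ECT2 by 0.50. Hypoxia and glycolysis genes rose in 20 of 35 cases and 9 fell, as adjusted over the list alone (median 0.18; adjusted p = 0.0346, and adjusted p = 0.295 with an estimated correlation). HK2, SLC2A3 and HK1 rose by 2.70, 1.36 and 1.05 and EGLN1 fell by 1.23. Replication-dependent histones rose in 8 of 12 cases with 0 falling, as adjusted over the list alone (median 0.63; adjusted p = 0.0159, and adjusted p = 0.288 with an estimated correlation). Of these 12, 4 were under 1 CPM in ICAM1-low. H2BC12 rose by 0.87, H2BC21 by 0.90 and H2BC4 by 2.15, and H2BC8, which passed the filter through ICAM1-high alone, had 43 counts against 1. Of 13 mitochondrially encoded genes, 11 fell and 0 rose, as adjusted over the list alone (median -0.24; adjusted p = 6.91e-04, and adjusted p = 0.546 with an estimated correlation). MT-CO3 fell by 0.40, MT-CYB by 0.34, MT-CO2 by 0.28 and MT-ATP6 by 0.27. Of 64 ribosomal protein genes, 33 fell and 10 rose, as adjusted over the list alone (adjusted p = 0.00633, and adjusted p = 0.628 with an estimated correlation). Their median was -0.099, and 0.074 with scaling by library size alone, and RPS16 (-0.58), RPL13A (-0.40) and RPL7 (-0.36) fell. Without ICAM1-low replicate 1, the calls of the G2/M (adjusted p = 0.201), histone (0.167), ribosomal (0.103) and hypoxia (0.0598) lists were lost, and without ICAM1-low replicate 2 those of the G2/M (0.255), histone (0.128) and hypoxia (0.0808) lists. The hypoxia call was also lost without ICAM1-high replicate 2 (0.0733) and, in a setting added after seeing the data, with the GC trend removed (0.519), and the ribosomal (0.926) and mitochondrial (0.0599) calls with scaling by library size alone.

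The remaining 12 lists were not called by camera. Many of their members changed, as did 59.7% of all genes tested. Adhesion and immune ligand genes rose in 14 of 24 cases and 6 fell (adjusted p = 0.0662). MCAM, L1CAM and CD276 rose by 2.67, 2.12 and 2.06, and ULBP1, also a member, fell by 3.78. That list was called without ICAM1-low replicate 1 (adjusted p = 0.0127) or 2 (0.0251), with no filter (0.0346) and with DESeq2 (0.0321). It was also called in both settings added after seeing the data, with genes under 1 CPM in ICAM1-low left out (0.0377) and with the GC trend removed (0.0293). Among 24 chemokine and cytokine genes, 13 rose and 8 fell (adjusted p = 0.894). Their median was 0.85, 0.32 without ICAM1-high replicate 1 and 0.25 at a mean of at least 1 CPM. The members with the smallest adjusted p, CXCL8 (-1.77), CXCL2 (-1.66), CXCL3 (-1.49) and LIF (-1.40), fell. Among 26 epithelial junction and keratin genes, 12 rose and 8 fell (adjusted p = 0.468). CLDN1 fell by 2.71 and KRT7 by 1.05, while the desmosomal gene DSP rose by 1.39 and KRT8 was 2.38-fold higher. Stem cell markers rose in 11 of 24 cases and 6 fell (adjusted p = 0.664). Although more members rose, the 4 with the smallest adjusted p, ALDH1A1, ITGA6 (-0.997), ABCG2 (-0.92) and BMI1 (-0.84), fell. Of 30 p53 targets, 17 rose and 8 fell (adjusted p = 0.468), FAS by 1.30 and PLK2 by 0.47 upward, whereas GDF15 and TNFRSF10B (-1.32) fell. Of 28 integrin and basement membrane genes, 12 rose and 12 fell (adjusted p = 0.977), among them ITGA5 (1.46), COL4A1 (1.35), ITGB5 (-1.001) and LAMB1 (-0.87). Of 25 TGF-beta targets, 9 rose and 12 fell (adjusted p = 0.678). Their median was -0.074, -0.006 without ICAM1-high replicate 1, -0.16 without ICAM1-high replicate 2 and 0.099 with scaling by library size alone, and their mean 0.37, and NEDD9 fell by 1.54.

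For 20 matrix proteases and related genes, 9 rose and 6 fell (adjusted p = 0.991). Although more members rose, the 4 with the smallest adjusted p, PLAU, ADAM9 (-0.88), ADAM17 (-0.88) and CTSL (-0.56), fell. The medians of this list (0.12) and of the integrin list (0.15) were positive although the camera direction of each was down. Without ICAM1-high replicate 1 the protease median was 0.046. In the settings added after seeing the data, the protease and integrin medians were -0.059 and 0.029 with genes under 1 CPM in ICAM1-low left out, and -0.093 and -0.26 with the GC trend removed. Lung epithelial and mucus genes rose in 8 of 17 cases and 5 fell (adjusted p = 0.664). LPCAT1 rose by 1.42 and MUC1 by 1.84, and AGR2 fell by 0.76 and MUC5AC by 0.70. Of 39 oxidative phosphorylation genes, 12 rose and 10 fell (adjusted p = 0.722), SDHA by 0.62 and UQCRC1 by 0.30 upward, CYC1 (-0.34) and UQCRFS1 (-0.31) downward. Of 12 class II genes 5 were tested, of which 3 rose and 1 fell (adjusted p = 0.417), CTSS by 0.97 and CIITA by 1.59, CD74 had 38 counts against 11, and HLA-DMB fell by 0.51. Of 20 leukocyte markers 5 were tested, of which 3 rose and 1 fell (adjusted p = 0.187), CD14 by 0.98 and ITGAX by 1.23, LAPTM5 had 75 counts against 4, and ITGAM fell by 0.50. CD74 and LAPTM5 passed the expression filter through ICAM1-high alone. The calls of CD74, HLA-DMB, ITGAM and PDGFRB depended on single libraries. Adjusted over the list alone, the counts of these 12 lists were the same except that 13 integrin genes rose.

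**Figure D4:**
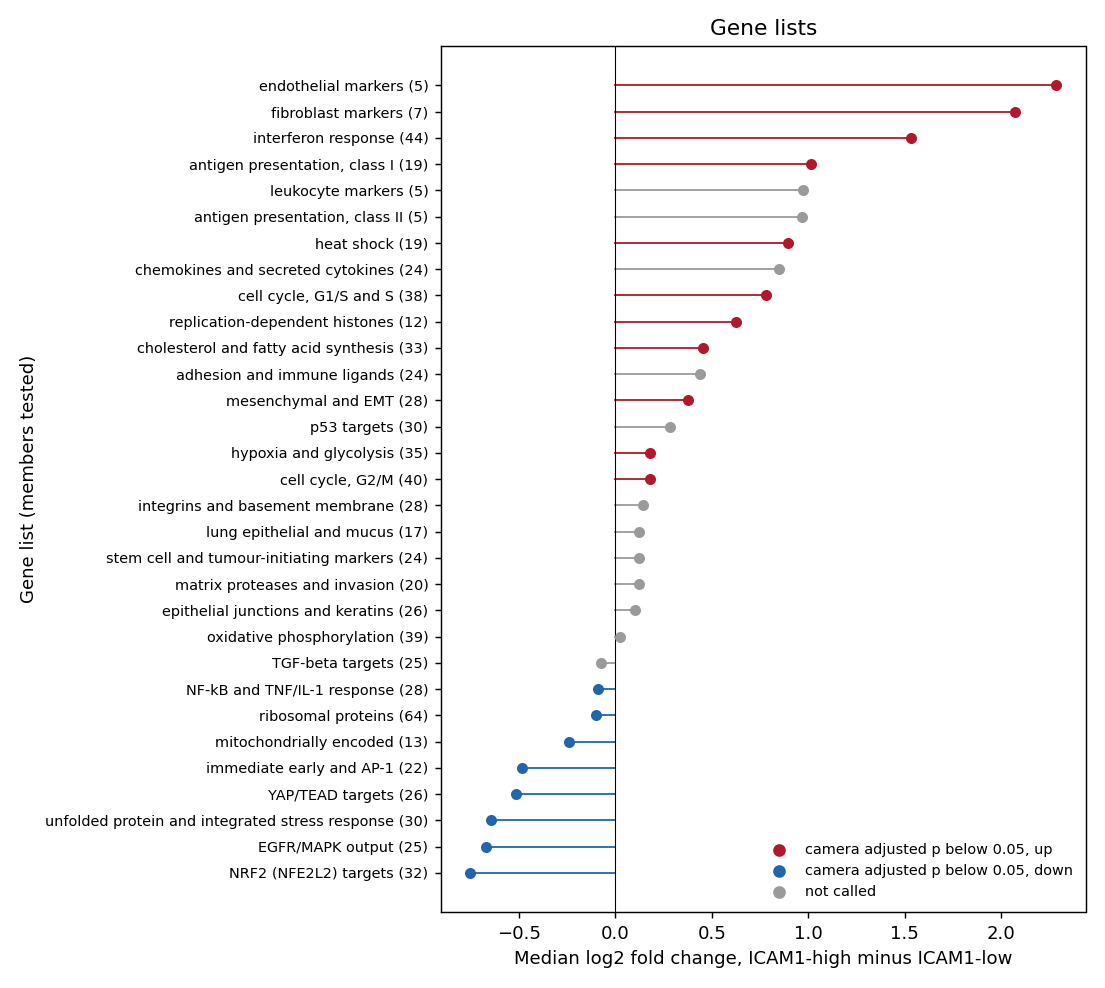
Median log2 fold change (horizontal axis, ICAM1-high minus ICAM1-low) of the members tested in each of 31 gene lists (vertical axis, members tested in brackets). Red and blue mark the 11 lists called up and 8 called down by camera with a preset correlation, led by the endothelial, fibroblast and interferon lists and by the NRF2 list. With an estimated correlation, a setting that could hardly call a list with 4 libraries, 0 lists were called.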

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

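ICAM1 kept its direction and call in the 12 alternatives in which it was fitted anew, at log2 fold changes of 4.52 to 4.61 when a library was left out. The count of called genes was 8383 to 9156 when a library was left out (4235 to 4535 higher, 4115 to 4621 lower), 7559 with DESeq2 and 9608 with limma-voom. Requiring at least 2-fold left 2517 genes, 1752 higher and 765 lower, and library size alone left 3124 lower. With genes under 1 CPM in ICAM1-low left out, chosen after seeing the data, 4037 were higher and 4749 lower. The replicate block gave 9812 calls, 4976 higher and 4836 lower, and 19 lists, with no list call changed. Deviations of same-numbered libraries correlated at 0.042 across genes, so the numbers are not shown to pair libraries. Camera called 19 lists, 15 to 18 when a library was left out and 0 with an estimated correlation, whereas fry, which does not compare a list with other genes, called 24. With 4 libraries the estimated correlation setting could hardly call a list. Fry gave an upward direction to the TGF-beta (median -0.074) and integrin (median 0.15) lists, each with adjusted p = 0.00363. Their mean log2 fold changes, 0.37 and 0.27, were also positive. The camera direction was down for both but called for neither (camera adjusted p = 0.678 and 0.977), and the cause of the difference was not tested. Lists lost elsewhere were the ribosomal (adjusted p = 0.926) and mitochondrial (0.0599) lists and the endothelial and fibroblast markers (0.0954 each) under library size alone, histones at a mean of at least 1 CPM (0.0673, median 0.34) and with genes under 1 CPM in ICAM1-low left out (0.0919, median 0.32), G2/M (0.0767), histones (0.119), endothelial (0.128) and fibroblast (0.104) markers with DESeq2, hypoxia (0.0540) and fibroblast markers (0.0589) with no filter, and mitochondrial genes with fry (0.0741). With the GC trend removed, chosen after seeing the data, the hypoxia median was -0.066 (adjusted p = 0.519), and lists still called had medians of 0.13 (mesenchymal), 0.52 (G1/S), 0.032 (G2/M), 0.34 (histones), -0.81 (immediate early and YAP/TEAD), -0.29 (ribosomal) and -0.41 (NF-kB). Library size alone gave medians of 0.35 (G2/M), 0.36 (hypoxia), -0.31 (immediate early) and -0.34 (YAP/TEAD), and with genes under 1 CPM in ICAM1-low left out the NF-kB median was -0.22, each still called. The cause of these losses was not tested. The fibroblast, endothelial, leukocyte and class II lists had under 5 members left, and so no test, at a mean of at least 1 CPM and with genes under 1 CPM in ICAM1-low left out. Of the named genes, CD74, HLA-DMB, ITGAM and PDGFRB lost their call in some settings and none reversed in those run. Genes near the floor of 3 counts limit folds to bounds.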

Other observations

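The tests in this part were chosen after the results were seen, apart from the planned scaling settings, and the gene groups in this paragraph were assembled then. Among genes of amino acid synthesis, transport and tRNA charging, 30 of 33 were lower in ICAM1-high and 1 higher, with a median log2 fold change of -1.31. Of all 16250 genes tested, 4771 were lower. The group was gathered with its values in view and was not tested as a list. Asparagine synthetase ASNS (log2 fold change -2.68, SE 0.17), mitochondrial PEP carboxykinase PCK2 (-2.46, SE 0.06), the folate enzyme MTHFD2 (-2.05, SE 0.04), the glutamine transporter gene SLC38A2 (-1.76, SE 0.04) and glycyl-tRNA synthetase GARS1 (-1.70, SE 0.04) fell. KRT17, a keratin of basal epithelium, was at 748 ± 57.0 CPM in ICAM1-high and 1.07 ± 0.0602 CPM in ICAM1-low (log2 fold change 9.45, SE 0.09). Of 3 genes known to be mutated in A549, the chromatin remodelling ATPase gene SMARCA4 was at 140.5 ± 11.8 CPM and 21.9 ± 0.661 CPM (2.68, SE 0.07), STK11 (0.15) did not pass the test and KEAP1 fell by 0.18.

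The pattern most in need of follow-up is the 81 genes counted in ICAM1-high and near 0 in ICAM1-low. Total counts were 1.06 times higher in ICAM1-high. At that ratio a gene with 100 counts in ICAM1-high would be expected at 94.3 in ICAM1-low, not at 3 or fewer, which argues against depth. RNA from cells other than A549 in both ICAM1-high libraries is a candidate explanation. The count that prompted it, 81 genes against 0 in the reverse direction, is what added RNA would give, but it is no separate evidence. Sorting on ICAM1 would keep such cells if they carried it. A549 is known to lack MTAP, CDKN2A and CDKN2B through a homozygous deletion. In ICAM1-low these had 0 to 9 counts over both libraries, while the 6 protein-coding flanking genes had at least 41 in each library and a median log2 fold change of 0.11. In each ICAM1-high library the 3 had at least 174 counts, which argues against a change of state in cells with that deletion for CDKN2A and CDKN2B, 2 of the 81. Other cells, or A549 cells without the deletion, stay open for them. For the other 79 genes, at most 9 of which lie on 1 chromosome, another source and a change of state cannot be told apart, because no DNA data were used and source and sort coincide.

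Among the 84 genes lower by at least 4-fold, with a median log2 fold change of -2.35, dilution of A549 RNA was tested as the whole cause. Transcripts known to be abundant in A549 (FGA, FGB, FGG, CPS1, MUC5AC, MUC5B, ALDH1A1, AKR1B10 and CYP24A1) had a median of -0.35, and the most reduced, CYP24A1, stood at -1.07 (SE 0.04), short of the -2 that a common dilution would need. Removal of the GC trend left the median of the 84 genes at -2.56, which argues against GC content. A difference between the sorted cells themselves stays open as a hypothesis, and so does another RNA source that differs in state as well as in origin. Apart from the NRF2 list, smaller falls were not weighed in this way. The NRF2 list, with a median of -0.75, lies within the range of the A549-abundant transcripts (-1.07 to -0.06) and shares AKR1B10 with them. A common dilution would lower these transcripts alike, yet FGA (-0.06), FGG (-0.10), MUC5B (-0.27) and their median (-0.35) fell less than the list. CYP24A1, ALDH1A1 (-1.06) and AKR1B10 (-0.79) fell more. Common dilution thus falls short of the list's whole median fall, but a partial share was not excluded.

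The interferon list was weighed against library scaling and other RNA. Its median stayed at 1.53 or more under 3 scalings, the main one included. The others shifted the median of all genes by -0.003 (DESeq2 size factors) and 0.17 (library size only). A choice among these scalings is thus too small to account for the rise, and a larger scaling error was not tested. Members at 1 CPM or more in ICAM1-low, 37 of 44, had a median of 1.35, and the other 7 a median of 4.91. The split is by the level in ICAM1-low, which also enters the fold change, so the larger rise of the 7 was partly fixed by it. Induction within A549 and RNA from other cells with active interferon genes could both give these values, and they cannot be told apart because the level of these genes in any other source is unknown.

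Across genes, fold change and transcript GC content had a Spearman correlation of 0.207, and genes are not independent replicates. Median log2 fold changes per chromosome ranged from -0.23 on chromosome 18 to 0.20 on chromosome 22.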
